A study of Zea mays with 4 samples.

How the data were processed

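Small RNA was sequenced from root tips of maize (Zea mays, cultivar Zhengdan 958) grown in nutrient solution. Per the labels' protocols, RNA of 18 to 30 nt was recovered from a gel, ligated to adapters, amplified over 18 PCR cycles and sequenced on an Illumina/Solexa Genome Analyzer. Each of 4 groups had 1 library: the early primary root (PRY, 3 days after germination), the later primary root (PRO, 15 days), the seminal root (SR, 7 days) and the crown root (CR, 15 days). Tips of 1 cm were taken, and the PRY, SR and CR roots were about 3 to 5 cm long. The read aligner, the miRNA reference release and the program that predicted candidate miRNAs are not given in the sources used here.

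The deposited table held 576 mature miRNAs with 1 value per library. The table's header calls these values TPM. The values as deposited had been normalized and were treated as RPM, reads of a miRNA for every 1000000 reads of a library total, because every value was a whole multiple of a fixed step in its library. If so, the steps gave totals of 10721082 reads for PRY, 11057522 for PRO, 11572637 for SR and 10920069 for CR. With them, 100% of the values came out as whole reads within 0.01 read, and the largest deviation was below 0.001 read. Whether a total covers all reads, or mapped or filtered reads alone, is not known. The table listed 321 known miRNAs in 29 families and 255 candidate miRNAs. The authors' names for the candidates are not printed here, and these miRNAs are described by their values. Of the known miRNAs, 75 were at 0 in all 4 libraries. The species prefix of the known names is left out below.

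Related mature miRNAs carried nearly the same values, since 1 read can match several members of a family. The 576 entries held 450 distinct sets of values, with identical entries of a family counted once. Sums over a family therefore count some reads repeatedly, and the entry with the highest mean in each family is used where a level of the family is given.

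A miRNA entered a comparison when it reached 10 RPM in at least 1 of its 2 libraries. It was counted as higher or lower when log2(RPM + 1) differed by 1 or more, which is a 2-fold difference on that scale. The pseudocount of 1 understates ratios of low miRNAs. Folds printed in the text are ratios of recovered reads scaled to the library totals, without a pseudocount. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals, and intervals of single values are exact Poisson. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. A fold against a library with 0 reads was bounded with a floor of 3 reads in that library, which is 0.259 to 0.280 RPM. With 1 library per group no test across replicates was possible and no p-value is given. Every difference compares libraries, not conditions, and has no replicate check.

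The 5 comparisons, 8 lists of miRNA families, the size rule, the rule for named miRNAs and most alternatives were chosen before the data were examined. The lists were phase change, auxin signalling, meristem and patterning, nutrient, copper-responsive, small RNA machinery, monocot families, and triggers of reproductive phased siRNAs as a check on other tissue. For each list the median log2 ratio was set among 10000 random lists of equal size matched on mean level, as a description of these libraries. Members of a family share reads while random lists mix families, so a list made mostly of 1 family reaches extreme percentiles easily. Named miRNAs were up to 8 with the highest and 8 with the lowest ratios among those counted and at 50 or more RPM in 1 library. Up to 4 families per list with the largest differences of family sums, and the 5 families with the largest sums in each library, were named as well. For such a family the highest entry is given. Any other entry below 50 RPM that is named was chosen after its values were seen.

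Ratios were computed with the library total and with another 5 scalings: the total over distinct miRNA entries, edgeR TMM factors (version 4.0.16), DESeq2 size factors (version 1.42.0), the miRNA total without the miR156 family, and the total of the highest entry per family. The last was chosen after seeing the data, as were a filter of 50 RPM, counting the highest entry per family, leaving out candidates, and calls on recovered reads. edgeR's quasi-likelihood test could not be run, because 1 library per group leaves no spread to estimate. The others were no filter, a filter of 100 reads, identical entries counted once, family sums and a pseudocount of 10. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, plots used matplotlib 3.10.9, and the factors came from R 4.3.3. The code for the calls was run on simulated data, in which 100% of the tested miRNAs changed 3-fold or 6-fold were recovered in each of the 5 comparisons and 0 unchanged ones were called. Simulated libraries differed by the planted changes and counting noise alone. The outcome therefore checks the code and gives no rate of false calls for libraries without replicates. The step that finds the library total recovered 20 of 20 simulated totals exactly.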

Results

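The small RNA population of the maize root tip was profiled in 4 libraries, 1 each from the early primary root (PRY, 3 days after germination), the later primary root (PRO, 15 days), the seminal root (SR, 7 days) and the crown root (CR, 15 days). Primary and seminal roots are formed in the embryo, and crown roots arise later from the shoot. Library totals, as recovered from the values, lay between 10721082 reads (PRY) and 11572637 reads (SR), so 1 read was worth 0.0864 to 0.0933 RPM (reads for every 1000000 reads of that total). The series as titled concerns miRNAs in root development and aluminium stress, and the 4 libraries bear on development alone. No group had a replicate.

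miR168a-5p, which targets the transcript of the silencing protein AGO1, was the most abundant miRNA in each library. It reached 67560 RPM in PRY, 60102 in PRO, 47529 in SR and 51319 in CR. In PRY this was 6.76% of the recovered total (95% exact interval 6.74 to 6.77), against 6.01% in PRO, 4.75% in SR and 5.13% in CR. miR156, which represses SPL transcription factors, and miR166, which represses class III HD-ZIP transcription factors, came next. miR156d-5p stood at 20801 RPM in PRY, 10527 in PRO, 8807 in SR and 4576 in CR. miR166a-3p stood at 15878, 11684, 9618 and 9969 in the same order. By sums over family members, which count shared reads repeatedly, miR156, miR166, miR168, miR167 and miR528 were the 5 leading families in each library. By these sums miR156 ranked above miR166 in PRY, PRO and SR, and below miR166 and miR168 in CR. By the highest entries, miR156d-5p lay above miR166a-3p in PRY alone. The highest entries of all families together made up 10.6% of the recovered total in PRY, 9.12% of PRO, 7.17% of SR and 6.77% of CR. Other scalings of the ratios are therefore given as well.

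**Figure D1:**
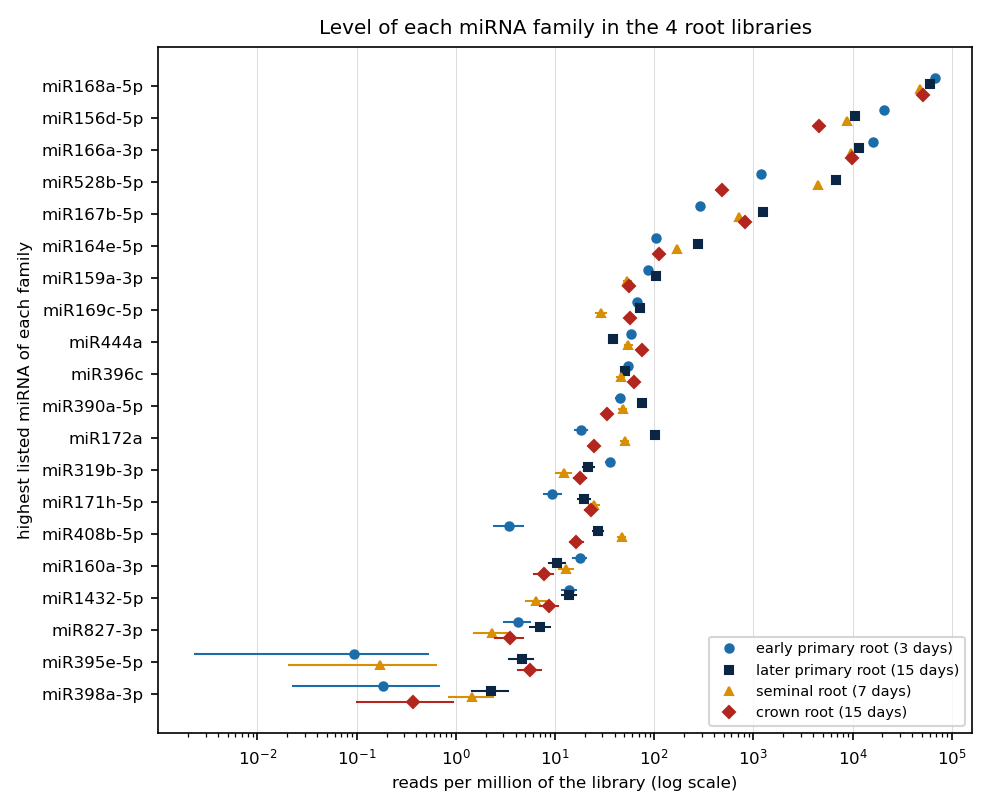
RPM (log axis) of the highest listed miRNA of 20 families in the 4 root libraries, with 1 point per library and bars for the 95% exact Poisson interval, which covers counting error only. Levels span from 67560 RPM for miR168a-5p in PRY to 0.0933 for miR395e-5p in the same library, and miR528b-5p spans 479 (CR) to 6830 (PRO).

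The later primary root library was compared with the early one to follow developmental stage within 1 root type. miR528, a monocot family that targets transcripts of copper proteins, was higher in PRO: miR528b-5p stood at 6830 against 1203 RPM, 5.68-fold (5.57 to 5.79), and miR528a-5p was nearly equal to it. miR172a, which represses AP2-like transcription factors, was 5.57-fold higher (4.79 to 6.51), at 103 against 18.5. Both miR167a-5p and miR167b-5p, which target auxin response factors, were 4.37-fold higher. miR164e-5p, which targets NAC transcription factors, was 2.59-fold higher (2.42 to 2.78), and miR156k-5p was 3.15-fold higher (3.08 to 3.22). Counted as lower in PRO were 9 other entries of miR156, among them miR156a-5p at 9686 against 20450 RPM, 2.11-fold (2.10 to 2.13). The star-strand product miR167h-3p was also lower, 3.47-fold (3.16 to 3.81).

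Of 102 miRNAs that reached the minimum, 19 were higher in PRO, 17 lower and 66 neither. Known families made up 16 of the higher and 16 of the lower ones. In the phase change list 7 of 19 were higher, 9 lower and 3 neither. Of the higher ones 6 belonged to miR172, among them miR172b-5p at 10.6-fold (7.13 to 16.4), and the 9 lower ones all belonged to miR156. The median of the list was -0.98 while its mean was 0.29, and the median over the sums of its 2 families was 0.85. In the auxin signalling list 5 of 18 were higher, all of them miR167, 4 lower and 9 neither, with a median of 0.76. miR160b-3p, from a family that targets another group of auxin response factors, was 3.43-fold lower (2.50 to 4.77). The 5p product miR160b-5p, below the minimum, was not lower, with 37 reads in PRO against 33 in PRY. miR390a-5p, which starts production of trans-acting siRNAs against auxin response factors, was 1.67-fold higher (1.49 to 1.87). miR393a-5p, which targets auxin receptors, was 1.84-fold higher (1.05 to 3.34) on 38 against 20 reads. All 3 measured copper-responsive entries were higher, 2 of them the nearly equal entries of miR528. The third was the 5p product miR408b-5p, 7.86-fold higher (5.58 to 11.4). The list's median of 2.50 lay at percentile 99.8 of matched random lists. miR408b-5p stood at 27.1 against 3.45 RPM and held most of the rise of its family, whose sum was 34.7 against 8.95. The remaining entries of the family together rose far less. The family targets plantacyanin and laccases, but targets of the 5p product were not examined.

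Of the meristem and patterning list 1 of 42 was higher, 3 lower and 38 neither, with a median of -0.16 that changed sign in 2 of 7 alternatives. The higher one was miR164e-5p. The lower ones were miR169o-5p, of the family that targets NF-YA subunits, and miR169a-3p and miR169b-3p, whose calls held with the library total alone. miR169o-5p had 143 reads in PRY and 0 in PRO, at least 49.2-fold lower. miR171h-5p, from a family that targets GRAS transcription factors, was 2.09-fold higher (1.65 to 2.68) by reads, but 0.99 on the log2 scale with the pseudocount. miR319b-3p, which targets TCP transcription factors, was 1.65-fold lower (1.40 to 1.95). miR166a-3p was 1.36-fold lower (1.35 to 1.37) with the library total, and turned to higher in 1 of the 6 scalings. No member of the small RNA machinery list (4 measured, median -0.17, changing sign in 2 of 7 alternatives) or of the monocot list (3 measured, median -0.58) was counted. miR168a-5p was 1.12-fold lower (1.12 to 1.13), with the opposite sign in 3 of 6 scalings. miR444a, which targets MADS-box transcription factors, was 1.51-fold lower (1.33 to 1.71). No single entry of a nutrient family reached the minimum, while the sum over miR395 entries, which counts shared reads repeatedly, was 24.2 RPM in PRO and 0.653 in PRY. miR395e-5p, of the family that targets ATP sulfurylase and a sulfate transporter, had 51 reads in PRO against 1 in PRY, a ratio of 49.4 (8.48 to 1991). miR398a-3p, which targets copper/zinc superoxide dismutase, had 25 against 2 reads, a ratio of 12.1 (3.02 to 106). Among candidate miRNAs, 1 stood at 1365 against 286 RPM, 4.78-fold higher (4.59 to 4.97). Another candidate was 2.93-fold lower (2.69 to 3.19), at 66.1 against 194. Of the 3 higher candidates, 1 was listed at 0 in PRY.

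The median log2 ratio was -0.17 with the library total and shifted by up to 0.49 with other scalings, which gave 29 higher and 6 lower with the miRNA total, 29 and 7 with TMM factors, 21 and 15 with DESeq2 factors, and 21 and 7 both without miR156 and with the highest entries. The 19 higher calls and 6 of the 17 lower ones held in all 6 scalings, while the calls of miR156a-5p and the like held in 2. Every scaling other than the library total moved the median upward, so the higher calls were hardly put to a test.

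**Figure D2:**
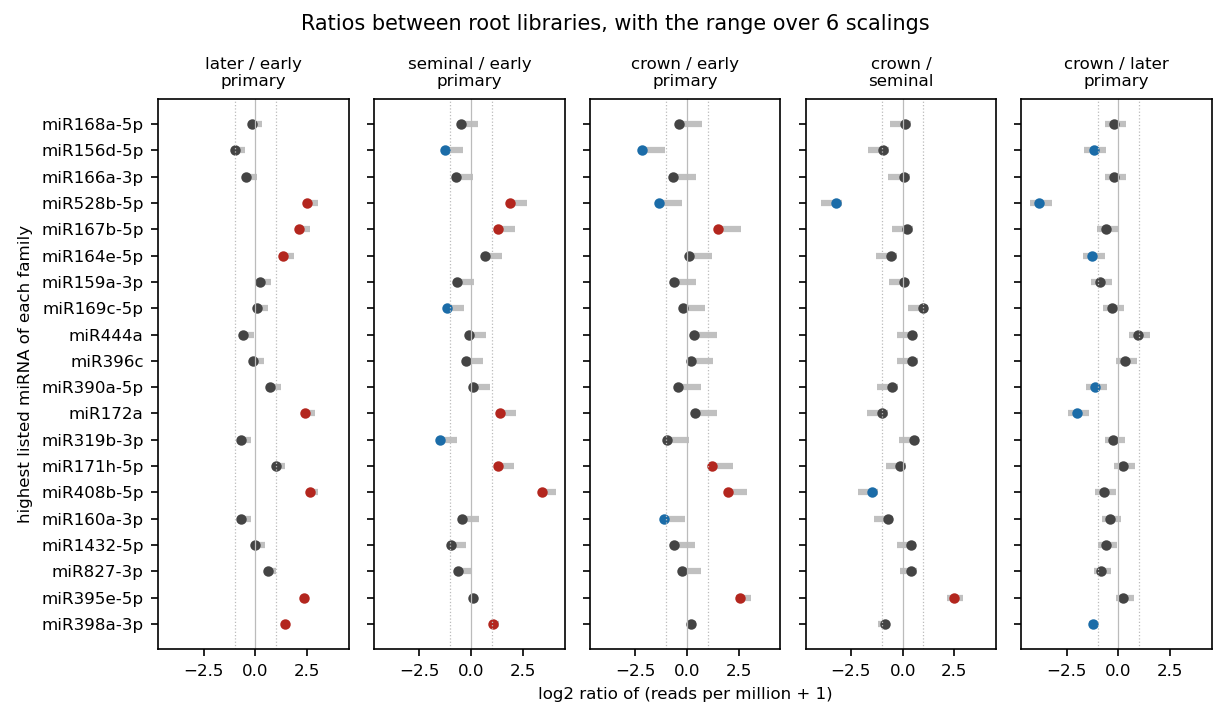
Log2 ratio of (RPM + 1) of the highest listed miRNA of 20 families in the 5 comparisons, with points for scaling to the library total and grey bars for the range over 6 scalings. Red points lie at 1 or above and blue points at -1 or below, whether or not the miRNA reached 10 RPM, and a bar that crosses 0, as for miR168a-5p in each comparison, marks a direction that turns with the scaling, while miR528b-5p lies at 2.50, 1.88, -1.33, -3.21 and -3.83 from left to right and keeps its sign.

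The seminal root library was compared with the early primary root library as a contrast of root type, with ages of 7 and 3 days. Again miR528b-5p was higher, at 4439 against 1203 RPM, 3.69-fold (3.62 to 3.76). miR408b-5p, at 46.8 against 3.45, was 13.6-fold higher (9.72 to 19.5). It held nearly all of the rise of its family, whose sum was 52.9 against 8.95 RPM. miR172a was 2.72-fold higher (2.31 to 3.21), miR167b-5p was 2.46-fold higher (2.36 to 2.57), and miR171h-5p was 2.64-fold higher (2.10 to 3.35). The sum over distinct miR171 entries was 41.6 against 25.4 RPM. Nearly all of its rise lay in miR171h-5p, at 24.9 against 9.42. miR156a-5p was 2.46-fold lower in SR (2.44 to 2.48), miR319a-3p 3.59-fold lower (2.89 to 4.51), and miR169c-5p 2.29-fold lower (2.01 to 2.62). miR169i-3p, with 4 reads in SR against 240 in PRY, was 64.8-fold lower (25.0 to 240), and miR169k-3p was 36.4-fold lower (19.5 to 76.6).

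Of 101 miRNAs measured, 18 were higher in SR, 30 lower and 53 neither, and 16 of the higher and 28 of the lower ones were known. The phase change list had 6 of 19 higher, all of them miR172, 11 lower, all of them miR156, and 2 neither. Its median was -1.24 (percentile 0.83 of matched lists, or 62.8 over family sums), its mean was -0.23, and the median over its 2 family sums turned to 0.16. miR156k-5p, unlike miR156a-5p, was 1.38-fold higher (1.35 to 1.41). In the auxin list 5 of 18 were higher, all miR167, 4 lower and 9 neither, with a median of 0.16. The lower ones were miR160b-3p (2.67-fold, 2.01 to 3.57), miR160g-3p, miR167h-3p (2.28-fold, 2.11 to 2.47) and miR167i-3p. The 5p product miR160b-5p, below the minimum, was lower as well, with 7 reads in SR against 33 in PRY (0.605 against 3.08 RPM). miR390a-5p differed by 1.07-fold, with an interval of 0.94 to 1.21 that includes 1.

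In the meristem and patterning list 2 of 42 were higher, 13 lower and 27 neither, with a median of -0.72 (percentile 1.75) that changed sign in 1 of 7 alternatives. The higher ones were miR171h-5p and miR171k-5p, and the lower ones were 9 entries of miR169 and 4 of miR319. Over the sums of its 7 families the list lay at percentile 12.9. miR164e-5p was 1.60-fold higher (1.48 to 1.72). miR159a-3p, which targets MYB transcription factors, was 1.63-fold lower (1.47 to 1.80) and turned to higher in 2 of 6 scalings. miR166a-3p was 1.65-fold lower (1.64 to 1.66) and turned in 1 of 6. miR396c, which targets growth-regulating factors, was 1.20-fold lower (1.06 to 1.35), with the opposite sign in 5 of 6 scalings. All 3 copper-responsive entries, the 2 of miR528 and the 5p product miR408b-5p, were higher, with a median of 1.88 (percentile 99.8). miR398a-3p, below the minimum, had 17 against 2 reads, a ratio of 7.87 (1.87 to 70.3). None of the 4 small RNA machinery entries (median -0.54, changing sign in 2 of 7 alternatives) or the 3 monocot entries (median -0.09, in 4) was counted. miR168a-5p was 1.42-fold lower (1.42 to 1.43), with the opposite sign in 3 of 6 scalings, and miR1432-5p was 2.14-fold lower (1.61 to 2.87) by reads and -0.99 on the log2 scale. The nutrient family miR395 was near the floor in both libraries, with 2 reads of miR395e-5p in SR and 1 in PRY. miR827-3p, which targets SPX-domain proteins, was 1.80-fold lower (1.09 to 3.02). The candidate at 286 RPM in PRY was 2.34-fold higher in SR (2.24 to 2.44), the one at 194 was 3.46-fold lower (3.17 to 3.79), and 1 of the 2 higher candidates was listed at 0 in PRY.

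Scaling changed the balance of calls: the median of -0.65 shifted by up to 0.79, and the split was 26 higher and 4 lower with the miRNA total, 21 and 7 with TMM factors, 19 and 9 both with DESeq2 factors and without miR156, and 20 and 7 with the highest entries. All 18 higher calls and 4 of the 30 lower ones held in the 6 scalings, and those of miR156a-5p, miR160b-3p, miR160g-3p, miR167h-3p, miR167i-3p and miR169c-5p held with the library total alone. Here too every other scaling moved the median upward, so the higher calls were hardly put to a test.

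The crown root library was also set against the early primary root library, with ages of 15 and 3 days. miR156a-5p stood at 4099 against 20450 RPM, 4.99-fold lower (4.94 to 5.04), and miR156d-5p was 4.55-fold lower (4.50 to 4.59). miR167a-5p was 2.87-fold higher in CR (2.76 to 2.99), miR164a-5p 2.13-fold higher (1.89 to 2.41) and miR171h-5p 2.43-fold higher (1.92 to 3.09). The sum over distinct miR171 entries was 36.9 against 25.4 RPM. All of its rise lay in miR171h-5p, at 22.9 against 9.42, and the other entries together were not higher. miR408b-5p was 4.75-fold higher (3.32 to 6.96), at 16.4 against 3.45 RPM. The remaining miR408 entries, below the minimum, were not higher. miR408a had 26 reads in CR against 30 in PRY, and miR408b-3p had 25 against 29. miR528b-5p was 2.51-fold lower (2.43 to 2.59), at 479 against 1203 RPM.

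Of 101 miRNAs, 17 were higher in CR, 25 lower and 59 neither, and 13 of the higher and 21 of the lower ones were known. In the phase change list 11 of 17 were lower, all miR156, and 6 were neither, with a median of -2.32 below that of every matched list, but at percentile 22.5 over family sums. miR172a was 1.33-fold higher (1.11 to 1.61) and miR156k-5p 1.20-fold higher (1.17 to 1.24). In the auxin list 5 of 18 were higher, all miR167, 3 lower and 10 neither, with a median of 0.69 that turned to -0.40 over family sums. The lower ones were miR160a-3p (2.30-fold, 1.77 to 3.02), miR160b-3p (2.94-fold, 2.18 to 4.01) and miR160g-3p. Below the minimum, the 5p product miR160b-5p was lower as well, with 6 reads in CR against 33 in PRY (0.549 against 3.08 RPM). miR390a-5p was 1.35-fold lower (1.17 to 1.55), with the opposite sign in 4 of 6 scalings, and miR393a-5p was 1.91-fold higher (1.09 to 3.46).

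The meristem and patterning list had 7 of 42 higher, 5 lower and 30 neither, with a median of -0.67 (percentile 1.16, or 10.8 with identical entries counted once and 35.8 over family sums) that changed sign in 1 of 7 alternatives. Higher were 5 entries of miR164 and 2 of miR171, and lower were 3 of miR169 and 2 of miR319. The 5 entries of miR164 had nearly the same values. The highest entry of that family, miR164e-5p, differed by 1.07-fold, with an interval of 0.98 to 1.16 that includes 1. miR169k-3p was 12.3-fold lower (8.33 to 18.7), miR169i-3p was 4.61-fold lower (3.41 to 6.33), and miR169o-5p, with 0 reads in CR, was at least 48.6-fold lower. miR319a-3p was 2.30-fold lower (1.90 to 2.80), while miR319b-3p was 1.99-fold lower (1.67 to 2.37) and turned to higher in 1 of 6 scalings. miR166a-3p was 1.59-fold lower (1.58 to 1.60) and also turned in 1. In the copper-responsive list miR408b-5p was higher and both entries of miR528 were lower, with a median of -1.33. None of the 4 small RNA machinery entries (median -0.22) or the 3 monocot entries (median 0.35) was counted, and each median changed sign in 3 of 7 alternatives. miR168a-5p was 1.32-fold lower (1.31 to 1.32), with the opposite sign in 4 of 6 scalings, and miR444a was 1.28-fold higher (1.15 to 1.42). Among nutrient entries, all below the minimum, miR395e-5p had 61 reads in CR against 1, a ratio of 59.9 (10.4 to 2404). miR399e-3p, which targets the phosphate regulator PHO2, had 14 reads in CR and 0 in PRY. Of the 4 higher candidates 2 were listed at 0 in PRY, and the candidate at 286 RPM in PRY was 3.93-fold higher in CR (3.77 to 4.09).

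The median of -0.64 shifted by up to 1.09, and the split was 40 higher and 13 lower with the miRNA total, 17 and 25 with TMM factors, 23 and 16 both with DESeq2 factors and without miR156, and 27 and 15 with the highest entries. All 17 higher calls and 13 of the 25 lower ones, with the 11 of miR156 among them, held in the 6 scalings, while the lower calls of miR528, miR160 and miR319 held in 2. Only TMM factors moved the median downward, with a shift of -0.02, so the higher calls were hardly put to a test.

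Crown and seminal root libraries were compared at 15 and 7 days, and miR528b-5p was 9.26-fold lower in CR (9.00 to 9.53), at 479 against 4439 RPM. miR408b-5p was 2.86-fold lower (2.41 to 3.40) and miR156a-5p 2.03-fold lower (2.00 to 2.05). miR167h-3p was 2.17-fold higher in CR (2.01 to 2.35), and miR169a-5p was 2.33-fold higher (1.83 to 2.98). Of 92 miRNAs, 6 were higher in CR, 17 lower and 69 neither, with 4 known ones among the higher and 14 among the lower.

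The phase change list had 11 of 19 lower and 8 neither, with a median of -1.02 (percentile 0.010, or 17.6 over family sums). The lower ones were 9 of miR156 and 2 of miR172, miR172b-5p among them at 2.61-fold (1.85 to 3.73). miR172a was 2.04-fold lower (1.76 to 2.36) by reads and just short of 2-fold on the log2 scale with the pseudocount. In the auxin list 2 of 16 were higher, miR167h-3p and miR167i-3p, and 14 neither. miR167b-5p was 1.17-fold higher (1.13 to 1.20) and turned to lower in 1 of 6 scalings, and miR390a-5p was 1.44-fold lower (1.26 to 1.65). In the meristem and patterning list 2 of 36 were higher, miR169a-5p and miR169b-5p, and 34 neither, with a median of 0.06 that changed sign in 1 of 7 alternatives. miR164e-5p was 1.49-fold lower (1.39 to 1.61) while miR164a-5p was 1.76-fold higher (1.57 to 1.97). miR319b-3p was 1.48-fold higher (1.19 to 1.85), miR396c was 1.37-fold higher (1.22 to 1.54), miR166a-3p was 1.04-fold higher (1.03 to 1.05) and miR168a-5p was 1.08-fold higher (1.08 to 1.08), and each turned to lower in 1 of 6 scalings. All 3 copper-responsive entries were lower, with a median of -3.21 (percentile 0.315, or 4.08 over family sums). None of the 4 small RNA machinery entries (median 0.38) or the 2 monocot entries (median 0.44) was counted, and each median changed sign in 1 of 7 alternatives. miR444a was 1.36-fold higher (1.22 to 1.51), turning to lower in 1 of 6 scalings. miR395e-5p had 61 against 2 reads, a ratio of 32.3 (8.57 to 273), and miR398a-3p 4 against 17, 4.01-fold lower (1.31 to 16.4). Of the 2 higher candidates, 1 was listed at 0 in SR.

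With the library total the median was 0.05, and it shifted by 0.28 with the miRNA total (15 higher, 5 lower) and by -0.73 with TMM factors (2 higher, 31 lower), while DESeq2 factors and the total without miR156 each gave 6 and 21, and the highest entries gave 9 and 9. Only 2 of the 6 higher and 5 of the 17 lower calls held in all 6 scalings, among them both of miR528 and that of miR408b-5p, while those of miR156a-5p held in 4.

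Crown root and later primary root libraries were both taken at 15 days, which sets root type and stage apart from seedling age. miR528b-5p was 14.3-fold lower in CR (13.9 to 14.7), at 479 against 6830 RPM. miR172a was 4.18-fold lower (3.65 to 4.79), miR156k-5p 2.61-fold lower (2.56 to 2.67), miR164e-5p 2.42-fold lower (2.27 to 2.59) and miR156a-5p 2.36-fold lower (2.34 to 2.39). miR167h-3p was 3.30-fold higher in CR (3.01 to 3.63). Of 95 miRNAs, 3 were higher in CR, 27 lower and 65 neither, with 2 known ones among the higher and 26 among the lower.

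Of the 19 phase change entries 18 were lower, 12 of miR156 and 6 of miR172, and 1 was neither, with a median of -1.24 (percentile 0.0050, or 17.6 over family sums). The exception was miR156j-5p, 1.26-fold lower (1.12 to 1.42) with the opposite sign in 4 of 6 scalings. In the auxin list 2 of 16 were higher, miR167h-3p and miR167i-3p, 2 lower, miR390a-5p (2.25-fold, 1.99 to 2.55) and miR390b-5p, and 12 neither, with a median of -0.07 that changed sign in 3 of 7 alternatives. miR167b-5p was 1.52-fold lower (1.48 to 1.56). The meristem and patterning list had 4 of 39 lower and 35 neither, with a median of -0.23 that changed sign in 4 of 7 alternatives. The lower ones were miR164e-5p, miR169c-3p, miR169i-3p (4.06-fold, 3.00 to 5.59) and miR169k-3p (7.76-fold, 5.22 to 11.9). The 5p product miR169i-5p, below the minimum, was not lower, with 53 reads in CR against 41 in PRO. miR164a-5p was 1.52-fold higher (1.36 to 1.69) and miR159a-3p 1.86-fold lower (1.69 to 2.06). miR166a-3p was 1.17-fold lower (1.16 to 1.18) and miR168a-5p 1.17-fold lower (1.17 to 1.18), both with the opposite sign in 4 of 6 scalings. In the copper-responsive list both entries of miR528 were lower and miR408b-5p, 1.66-fold lower (1.37 to 2.00), was neither, with a median of -3.83 (percentile 0.265, or 6.70 over family sums). None of the 4 small RNA machinery entries (median -0.01, changing sign in 4 of 7 alternatives) or the 3 monocot entries (median 0.93, in 1, at percentile 98.1, or 76.3 with identical entries counted once and 68.9 over family sums) was counted. miR444a was 1.93-fold higher (1.72 to 2.18). miR395e-5p, with 61 against 51 reads, gave a ratio of 1.21 (0.82 to 1.79) that includes 1 and turned in 1 of 6 scalings, and miR398a-3p, with 4 against 25 reads, was 6.17-fold lower (2.13 to 24.4). The 1 higher candidate was listed at 0 in PRO.

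The median of -0.31 shifted by up to 0.59 upward and 0.43 downward, and the split was 10 higher and 10 lower both with the miRNA total and with the highest entries, 3 and 41 with TMM factors, and 5 and 11 both with DESeq2 factors and without miR156. All 3 higher and 10 of the 27 lower calls held in the 6 scalings, among them those of miR528 and miR172, while those of miR156a-5p, miR164e-5p, miR169c-3p, miR390a-5p and miR390b-5p held in 2 and that of miR156k-5p in 4.

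The check on other tissue gave next to no signal, but it covered reproductive tissue alone and does not bear on carry-over from other parts of the seedling. miR2118 and miR2275, which trigger phased siRNAs in reproductive organs, had at most 1 read per entry in any library.

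**Figure D3:**
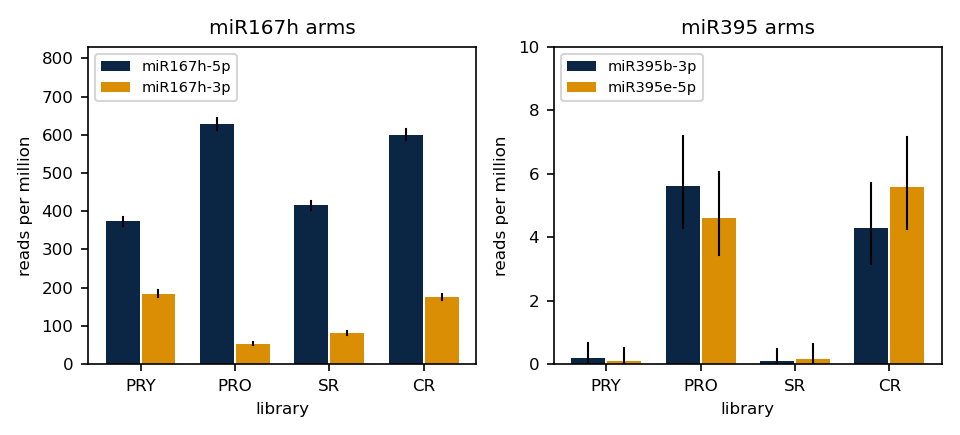
RPM of the 5p and 3p products of miR167h (left) and of miR395b-3p and miR395e-5p (right) in the 4 libraries, with bars from 0 and lines for the 95% exact Poisson interval. miR167h-3p was at 185 RPM in PRY and 53.3 in PRO while miR167h-5p was at 373 and 628, and both miR395 products were at 4.30 or more in PRO and CR and below 0.2 in PRY and SR.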

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

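No paired analysis was possible because each group had 1 library and the labels carry no replicate numbers. The counts of miRNAs at least 2-fold different were 36 (PRO against PRY), 48 (SR against PRY), 42 (CR against PRY), 23 (CR against SR) and 30 (CR against PRO). In that order, no filter gave 110, 111, 126, 92 and 76, as more low miRNAs entered. Sums per family gave 10, 10, 14, 9 and 6, as fewer items were counted. Alternatives chosen after seeing the data were the highest entry per family, with 9, 12, 14, 7 and 7, again over fewer items, and recovered reads with a minimum of 20 reads and an interval that excludes 1, with 93, 88, 96, 81 and 65. Also chosen then, a filter of 50 RPM left 26 for SR against PRY, 23 for CR against PRY and 12 for CR against SR, as fewer miRNAs were tested. A pseudocount of 10 gave 27 for CR against PRY, as it shrinks ratios of low miRNAs. For SR against PRY the miRNA total gave 30, TMM factors, DESeq2 factors and the total without miR156 gave 28 each, and the highest entries gave 27. For CR against PRO both DESeq2 factors and the total without miR156 gave 16. Each of these scalings moved all log2 ratios of a comparison upward by nearly the same amount. The amount was 0.49 to 0.83 for SR against PRY, and 0.38 (DESeq2 factors) and 0.35 (without miR156) for CR against PRO. Lower calls near the cutoff then fell short of it, such as miR156a-5p at -1.30 in SR against PRY and -1.24 in CR against PRO. Counts stayed within 1.5 times under a filter of 100 reads, with identical entries counted once and with candidates left out, in all 5 comparisons. The filter of 100 reads lies close to the minimum of 10 RPM at these depths, so it could hardly move the counts. Candidates were at most 14 of the miRNAs tested in a comparison, so leaving them out could move the counts little. The number of lists whose median lay outside the central 95% of matched random lists was 2, 3, 2, 2 and 4 in the same order. Sums per family gave 1, 1, 0, 0 and 0, since a family then counts once. No filter gave 1 for SR against PRY and 2 for CR against PRO. Identical entries counted once gave 1 for CR against PRY and 2 for CR against PRO. For CR against PRY the miRNA total, DESeq2 factors and the total without miR156 each gave 1. The cause was not tested. The median of the phase change list for SR against PRY, -1.24, turned to 0.16 with sums per family, where miR156 and miR172 count once each. Family sums with identical entries counted once came to 334318 RPM in PRY, 233828 in PRO, 187648 in SR and 153605 in CR, and to 490785, 351145, 282123 and 244986 with all entries summed. For single miRNAs, 300 values were labelled moved under an alternative and 141 the same, and for list medians 165 moved, 44 were the same and 1 reversed, a label kept for medians of at least 1 in size that change sign. A value was labelled moved when it left the 95% counting interval of the main value, so a change of scaling moves well-counted miRNAs by construction. Of the 141 the same, 63 came from recovered reads, which gave that interval themselves. The labels therefore do not measure robustness. Of the 210 list medians under alternatives 38 had the opposite sign, in 19 of 30 lists. Depth limited the families below 10 RPM, where 1 read was worth 0.0864 to 0.0933 RPM.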

Other observations

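All tests in this part were chosen after the results were seen. In miR167h the listed 3p reads made up 33.1% of the 5p and 3p reads in PRY, 7.81% in PRO, 16.3% in SR and 22.7% in CR. A share within 1 library does not depend on its scaling, but entries of other miR167 members have nearly the same 5p reads and miR167i has the same 3p reads, so the shares are not of 1 precursor.

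Of 255 candidate miRNAs, 156 were listed above 0 in 1 library alone: 52 in PRY, 25 in PRO, 34 in SR and 45 in CR. Among 455 candidate values above 0 there were 0 of 1 to 4 reads, against 205 of 826 values (24.8%) of known miRNAs, consistent with a minimum of 5 reads for listing a candidate in a library. The median was 8 reads in candidates listed in 1 library and 35.3 in those listed in 4. There were 6 candidates at 0 in 1 library and at 20 or more reads in each of the others. A prediction step run separately for each library and a difference between roots both remain open, and no biological explanation was tested.

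miR395 was higher in both 15-day libraries. miR395e-5p had 51 reads in PRO and 61 in CR, against 1 in PRY and 2 in SR, and miR395b-3p had 62 and 47, against 2 and 1. Counting error of independent reads is argued against for miR395e-5p, since the lowest lower bound of its 4 read ratios was 7.02. That bound does not cover reads copied by PCR, and the pattern was picked after its values were seen. Of 187 entries with 20 or more reads in 1 library, candidates among them only if listed in all 4, 19 split the 15-day libraries from the younger ones by 2-fold, 18 of them miR395, whose members share reads, and 1 a candidate. Another 8 split the primary root libraries from the others, and 6 split PRY and CR from the others. Seedling age and other differences shared by the 15-day libraries remain open and were not tested, since each group had 1 library.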
